A study of Sciaenops ocellatus with 24 samples.

How the data were processed

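Pooled whole red drum larvae were sampled at 48 h post fertilization after exposure to dilutions of oil in 1 L beakers, and libraries were made from 200 ng of total RNA with a directional kit, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.33, RSEM, Bowtie 1.1.1 and DESeq, without saying in which role or order; the version of RSEM and of DESeq, the assembly and any annotation are not given in the sources used here. Each sample's table holds RSEM expected counts, which the authors deposited without normalization, for 515740 transcripts of 433807 assembled genes, per the file headers. All identifiers begin with the prefix that the Trinity assembler writes. The authors also deposited a table for each comparison of a concentration with its control. Per the file headers these hold mean signal values of the control and the treated libraries, a log2 ratio of control over treated, and a p-value adjusted by a method that is not stated. The deposited mean signal values were found to be weighted sums of the deposited counts, and the weights were solved from the values. The tables of 2.500% and 5.000% list only transcripts with an adjusted p-value under 0.05 as deposited by the authors.

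The expected counts were summed per gene and rounded to whole numbers. Replicate 3 at 2.500% and at 0.270% was given as a table per gene that equalled the sums of replicate 2 within 0.1 counts for all 433807 genes, with largest differences of 0.06 and 0.03 counts, so each pair entered as 1 library. The library totals ran from 56343801 to 112040706 counts. In the comparisons at the middle concentrations 2 libraries therefore stood against 3.

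The design was fixed before the data were examined. Within each series, 1 model with a coefficient per group was fitted to the 11 libraries, and each concentration was compared with the control by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with TMM scaling and filterByExpr. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are said to have passed. A slope on the concentration in percent was fitted in the same way. The difference between the effects at the highest concentrations and the difference between the controls came from 1 fit to all 22 libraries. CPM values were computed with the TMM factors. Standard errors (SE) were computed as the size of the log2 fold change divided by the square root of the test's F statistic. They therefore restate the test and are not a separate estimate of spread.

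Genes were to be named by a rule fixed before the data were examined: the largest fold changes in each direction among genes that passed, with a mean of at least 10 counts per library and with every exposed library on the same side of every control. For features without a gene name the rule took at most 2 in each direction per comparison. Of these, identifiers are printed for no more than 2 genes that rose and 2 that fell in all, and these 4 were chosen after their values were seen, by the smallest p of the m slope, because many genes of the rule lay near the limit of detection. The values of several genes of the rule are given without identifiers. A set of 22 gene lists with 817 entries, and a check of the oil-responsive gene CYP1A, had also been fixed, but the files do not pair identifiers with gene symbols, so the lists were not tested and no listed gene was looked up. The alternatives that concerned the lists were not run.

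The overlap of 2 comparisons was set beside the overlap of independent lists of the same sizes. Such lists take all genes as equally likely to pass, whereas genes that passed were more abundant than the rest. An excess over them may in part reflect which genes are easier to detect. For comparisons that share controls, unchanged groups were simulated 3 times against shared controls, and the correlation and covariance of fold changes across genes were computed in the same way. Principal components were computed within each series. Their relations to mean gene length, total counts and concentration were tested with 100000 permutations, 6 relations in all. Mean gene length was weighted by counts and computed from the same counts as the components.

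The test was tried on simulated data with 200 genes changed by 1.5-fold, 2-fold or 4-fold. In the simulation of 5.000% against control, with 157508 genes, 1.49%, 23.9% and 69.7% of the genes changed by these folds were recovered, and 2 of 65 calls were false. In that of 0.540% against control, with 110868 genes, 7.46%, 37.3% and 63.6% were recovered, and 6 of 78 calls were false. Changes of 1.5-fold were therefore mostly missed in these simulations. With only 200 genes changed the cut on p was stricter than in the real comparisons, where 4069 and 13421 genes passed. The simulated genes also varied independently of each other. These rates of recovered and false calls therefore do not carry over to the real comparisons.

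The alternatives were DESeq2 1.42.0, relative-log-expression factors in place of TMM, no filter on low counts, at least 10 counts in 3 libraries, a minimum fold change of 2, only the 2 groups compared, transcripts in place of genes, the rank of the concentration, a replicate block, and leaving out each library in turn. Added after the data were seen were mean gene length as a covariate, replicate 2 entered as a pair, and TMM factors set within each series. The tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and the figures were drawn with matplotlib 3.10.9.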

Results

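Red drum (Sciaenops ocellatus), a coastal marine fish, were exposed from just after fertilization to dilutions of a high-energy water-accommodated fraction (HEWAF), a dispersion made by blending crude oil into seawater, and pooled whole larvae were sequenced at 48 h post fertilization. The study used slick oil and source oil from the Deepwater Horizon spill. The samples form 2 series, marked s and m in their titles. The labels used here do not say which mark is the slick oil and which the source oil, so the series are called s and m throughout. The s series held a control and concentrations of 1.250%, 2.500% and 5.000%, and the m series a control and concentrations of 0.135%, 0.270% and 0.540%. The labels list 24 samples in 8 groups, with 3 replicates in each group. The tables of replicate 3 at 2.500% and at 0.270% held the values of replicate 2 of the same group for all 433807 assembled genes within 0.1 counts, which is less than sampling noise, so each pair was counted as 1 sample. This left 22 distinct libraries, with n = 2 at both middle concentrations and n = 3 elsewhere. The libraries held between 56343801 and 112040706 estimated counts each, and the 10 most abundant genes took between 6.52% and 8.51% of them. The genes are features of a transcriptome assembled without a reference and carry identifiers that the files do not pair with gene names, so no gene family or pathway is named and the response is described through sets of genes. The labels do not state for each library that it came from its own beaker, so p-values measure the spread between these samples, which may in part be technical.

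The first question was how many genes changed at each concentration of the s series. At 1.250%, 462 of 165854 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 335 of them higher and 127 lower than in the controls. At 2.500%, 3956 passed, with 1295 higher and 2661 lower, and at 5.000%, 4069 passed, with 3191 higher and 878 lower. The genes that rose had a median abundance of 9.06 CPM (counts scaled to library size) at 1.250%, 7.17 at 2.500% and 6.96 at 5.000%, against 0.427, 0.414 and 0.415 for the genes that did not pass. Changes of at least 2-fold made up 76.4%, 59.9% and 58.3% of the genes that passed at the 3 concentrations. Single libraries set much of these counts: without replicate 3 at 5.000% the count there was 20338, and without replicate 1 at 2.500% it was 917 with the majority turned, 771 higher and 146 lower, through the loss of lower genes and with none reversed. The majority at 2.500% also turned with transcripts in place of genes, 680 higher and 335 lower, and with mean gene length as a covariate, added after the data were seen, 22027 higher and 15751 lower. With that covariate 2280 of the 3956 were kept. All libraries at 1.250% and at 2.500% had a lower mean gene length than every s control, so the covariate is partly confounded with both concentrations. That covariate also raised 1.250% to 4542 and 5.000% to 28434, and with only the 2 groups compared 1.250% gave 2803 and 2.500% gave 23826. Leaving out any 1 control library brought 5.000% down to between 2313 and 2444 and 2.500% down to between 1594 and 1732, 2.500% gave 1833 without replicate 2, and 1.250% gave between 248 and 284 without control replicate 1 or 2 or 1.250% replicate 2 or 3.

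In the m series the count of changed genes grew at each step. At 0.135%, 322 of 116687 genes tested passed, 257 higher and 65 lower. At 0.270%, 2440 passed, 1959 of them higher and 481 lower. At 0.540%, 13421 passed, 7917 of them higher and 5504 lower, and 51.1% of these changed by at least 2-fold. Genes that rose at 0.135% had a median abundance of 19.9 CPM and those that rose at 0.540% one of 4.14 CPM. Without replicate 3 at 0.135%, all 322 were kept in the same direction and 1514 genes passed, 459 higher and 1055 lower, so the majority turned through added lower genes. There, 214 passed without replicate 2 and 194 without control replicate 2. Without control replicate 2 the count at 0.270% was 1106, and at 0.540% it was 10907. Without any 1 other control or any 1 library at 0.540%, the count at 0.540% was between 6492 and 8493. Among the other settings the count at 0.135% lay between 120 and 1746 and at 0.270% between 1158 and 18291. The majority turned at 0.270% with mean gene length as a covariate, 5271 higher and 6107 lower, and at 0.540% with only the 2 groups compared, 11661 higher and 14288 lower. A set of 102 genes was chosen by their level in m control replicate 1. Summed, they stood at 12500, 720 and 107 CPM in m control replicates 1, 2 and 3 and at most 21 CPM in any other library. They gave 26, 33 and 78 of the genes that passed at the 3 concentrations. Choosing them by their level in a control favours calls among the lower genes. The 65 lower genes at 0.135% may thus rest in good part on this set.

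**Figure D1:**
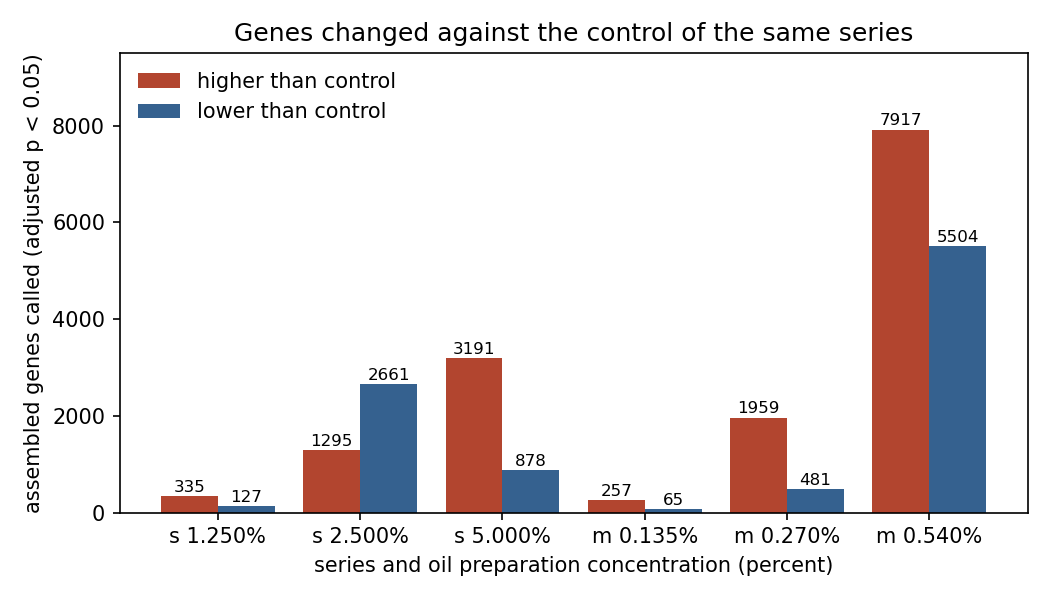
Number of assembled genes that passed an adjusted p of 0.05 in edgeR's quasi-likelihood test at each concentration of the s and m series (x axis) against the control of the same series, split into genes higher (red bars) and lower (blue bars) than the control. In the s series the genes that rose numbered 335, 1295 and 3191 and in the m series 257, 1959 and 7917, while the genes that fell numbered 2661 at 2.500% and 878 at 5.000%.

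A linear slope on the concentration was then fitted within each series, to ask which genes followed the concentration. In the s series 4793 genes had a slope, 3762 rising with concentration and 1031 falling. In the m series 16053 genes had a slope, 8909 rising and 7144 falling. Among the 112614 genes tested in both series, 2016 rose and 505 fell with concentration in both, where independent lists of these sizes would share 274 and 58.5, and 90 had opposite slopes. Genes with a slope were more abundant than the rest in both series, which may by itself raise such sharing. The m majority turned with the rank of the concentration, 9742 rising and 10350 falling, and without a filter on low counts, 11115 rising and 11447 falling. With mean gene length as a covariate, added after the data were seen and partly confounded with concentration in the m series, the m count was 8196, with 6504 of the 16053 kept, and the s count 14472. Without replicate 3 at 5.000% the s count was 10520, and without any 1 control it was between 2941 and 3099. Without replicate 3 at 0.540% the m count was 6696, without replicate 1 there 10442, and without control replicates 1 and 3 in turn 9185 and 10261.

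A common set of genes responded at every concentration tested. In all 6 comparisons with control, 180 genes were higher and 22 genes were lower. The 180 genes rose by a median of 1.30, 1.76 and 2.16 on the log2 scale at 1.250%, 2.500% and 5.000%, and by 1.09, 1.61 and 1.96 at 0.135%, 0.270% and 0.540%. The fitted change grew at each step for 169 of the 180 genes in the s series and for 155 of them in the m series. Their summed counts were set against the library total multiplied by its TMM factor, a percent called their share here. It is not the fraction of a library's own counts, and the TMM factors at 5.000% were 0.86, 0.823 and 1.11. The share was 0.464% ± 0.015 (SD, n = 3) in the s controls and 0.521% ± 0.016 (SD, n = 3) in the m controls. Their share was 1.22% ± 0.12 (n = 3) at 1.250%, 1.63% ± 0.27 (n = 2) at 2.500% and 2.16% ± 0.45 (n = 3) at 5.000%. In the m series it was 1.15% ± 0.13 (n = 3) at 0.135%, 1.64% ± 0.16 (n = 2) at 0.270% and 2.06% ± 0.089 (n = 3) at 0.540%. In every exposed library the share lay above that of every control library. The 22 genes fell from 0.455% ± 0.016 (SD, n = 3) in the s controls to 0.230% ± 0.041 (n = 3) at 5.000%, and from 0.589% ± 0.016 (n = 3) in the m controls to 0.281% ± 0.006 (n = 3) at 0.540%. In the s series the share of the 22 genes was already 0.234% ± 0.016 (n = 3) at 1.250%. The change grew at each step for 8 of the 22, against 19 of the 22 in the m series. At 5.000% the shares of the 22 genes were 0.247%, 0.26% and 0.184%, the lowest in the library with the TMM factor of 1.11. Whether the fall in the s series was graded may therefore depend on the scaling and is left open. Choosing the set for passing at 1.250% also favours a large first step. Both sets were chosen for passing in these same libraries, so their medians and shares overstate what new samples would show. Without any 1 library, between 124 and 200 genes were higher and between 9 and 31 lower at all 6 concentrations, the 9 without replicate 3 and 14 without replicate 2 of the m controls. Where an exposed library was left out, only the comparison at its own concentration was refitted, and the other comparisons kept the full fit. With only the 2 groups compared, 96 of the 180 and 12 of the 22 were kept.

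**Figure D2:**
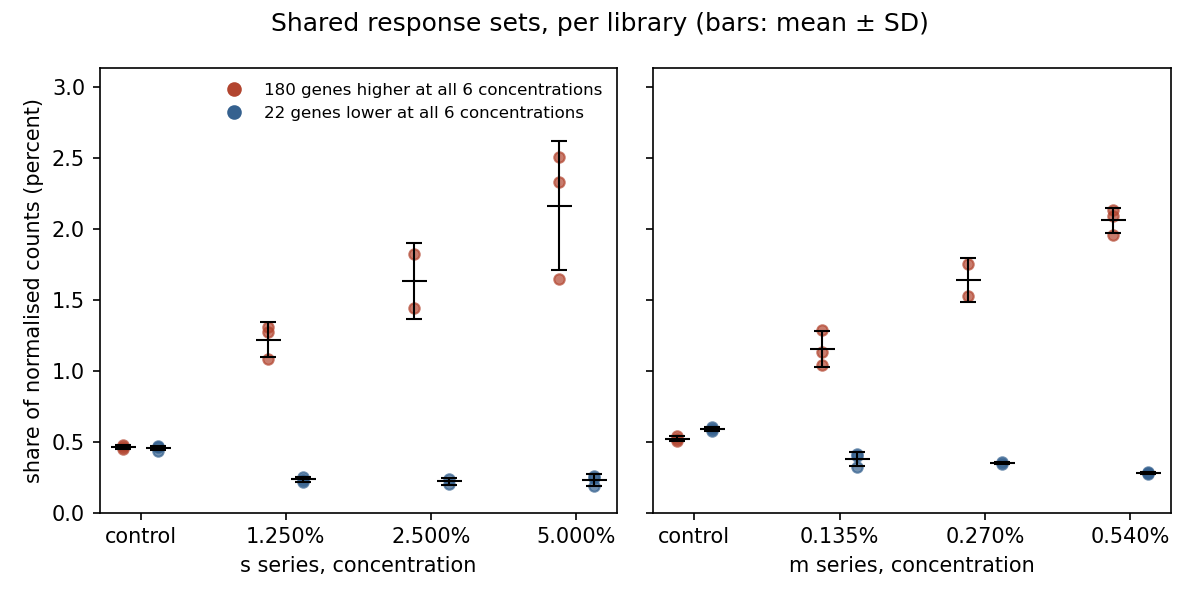
Summed counts of the 180 genes called higher (red) and the 22 genes called lower (blue) at all 6 concentrations, in each library (points), with the mean and SD of each group (black), for the s series (left) and the m series (right). The y axis gives them as a percent of the library total multiplied by its TMM factor, which is not a fraction of the library's own counts. This value for the 180 genes went from 0.464% in the s controls to 2.16% at 5.000% and from 0.521% in the m controls to 2.06% at 0.540%.

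Of the genes with a slope, 4 are named here by their identifiers, chosen after their values were seen, as the genes with the smallest p of the m slope in each direction. TRINITY_DN197545_c0_g1, with a transcript of 2593 bp, stood at 8.87 ± 0.29 CPM (SD, n = 3) in the s controls and 49.8 ± 10 (n = 3) at 5.000%, and at 9.30 ± 0.60 (n = 3) in the m controls and 117 ± 28 (n = 3) at 0.540%. Its rise at 0.540% was 3.65 on the log2 scale (SE 0.16, adjusted p = 6.8e-09 in edgeR's quasi-likelihood test). TRINITY_DN210490_c0_g1, of 4495 bp, rose from 45.9 ± 1.2 CPM (SD, n = 3) to 175 ± 42 (n = 3) in the s series and from 40.3 ± 1.8 (n = 3) to 170 ± 5.7 (n = 3) in the m series between control and highest concentration. TRINITY_DN220631_c0_g1, of 1110 bp, fell from 25.0 ± 0.73 CPM (SD, n = 3) in the s controls to 3.57 ± 0.29 (n = 3) at 5.000%, and from 38.0 ± 2.4 (n = 3) in the m controls to 4.81 ± 0.42 (n = 3) at 0.540%. TRINITY_DN277807_c0_g1, of 486 bp, fell from 40.8 ± 1.0 to 19.2 ± 3.2 CPM (SD, n = 3 each) in the s series and from 85.6 ± 9.4 to 12.2 ± 1.4 CPM (SD, n = 3 each) in the m series, and the difference between the series at the highest concentrations was -1.94 on the log2 scale (SE 0.20, adjusted p = 1.7e-04 in edgeR's quasi-likelihood test), against a median of -0.53 over all genes. Choosing this gene by the m slope favours a larger m effect. It also had the smallest p of that difference among the genes below 0, so its p there is not an independent test. The first 3 of the 4 named genes passed at all 6 concentrations.

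The naming rule set before the data were examined picked the largest fold changes, and the increased genes given here were near the limit of detection. The most increased gene at 0.135% went from 0.0549 ± 0.022 CPM (SD, n = 3) in the m controls to 0.419 ± 0.054 (n = 3) at 0.135% and 0.683 ± 0.13 (n = 3) at 0.540%, and from 0.0765 ± 0.012 (n = 3) to 0.537 ± 0.21 (n = 3) between control and 5.000%. The 2 most increased genes at 0.540% had 0 counts in all 3 m controls and 1.09 ± 1.1 and 0.884 ± 0.92 CPM (SD, n = 3 each) at 0.540%. The most increased gene at 2.500% had 0 counts in the s controls and stood at 0.584 ± 0.10 CPM (SD, n = 2) at 2.500% and at 1.26 ± 0.23 (n = 3) in the m controls. The most decreased gene at 0.540% stood at 820, 45.1 and 6.95 CPM in m control replicates 1, 2 and 3 and at 0 in the 3 libraries at 0.540%, so its mean of 291 ± 460 CPM (SD, n = 3) rested on 1 library.

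Within a series, comparisons share their control libraries, which by itself makes them alike. Fold changes at 1.250% and 5.000% correlated across genes with r = 0.62, against 0.51 for simulated unchanged groups with shared controls, and the covariance was 0.107 against 0.0746 simulated. At 0.135% and 0.540% r was 0.71 against 0.52 simulated, with a covariance of 0.332 against 0.0887. Genes higher at both 1.250% and 5.000% numbered 323, where independent lists would share 6.45, and genes higher at both 0.135% and 0.540% numbered 257, where independent lists would share 17.4. Simulated unchanged groups gave 0 genes called at both, which follows from having nothing to call and is no measure of the overlap that shared controls bring. The 3 controls of a series could not be divided with at least 2 in each part, so part of this excess may come from the shared controls. Genes are not independent replicates, so no p is given for these correlations.

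Between the series no control library was shared, and the comparison asked whether the 2 oils moved the same genes. At the highest concentrations, 2505 genes passed in both series and 2451 of them, 97.8%, moved the same way. Fold changes had the same sign in both series for 90.4% of the genes that passed at 5.000% and 70.2% of those that passed at 0.540%. Over all genes tested in both series the share was 45.3%. The overlap held 1974 genes higher in both, where independent lists would share 207, and 477 lower in both, where they would share 38.8. At the lowest concentrations 183 genes were higher and 22 lower in both, with none opposite, against 0.755 and 0.0448 for independent lists, and at the middle concentrations 628 were higher, 116 lower and 7 opposite. Genes that passed were the more abundant ones in both series, so part of each excess may come from which genes are easier to detect. Across all 112614 genes tested in both, most of which did not pass in either, the correlation of fold changes was 0.14 at the highest and -0.10 at the middle concentrations. The 2 series were given at different concentrations, so these values are set side by side and do not compare potency. Without replicate 3 at 5.000%, the genes shared at the highest concentrations numbered 5532.

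**Figure D3:**
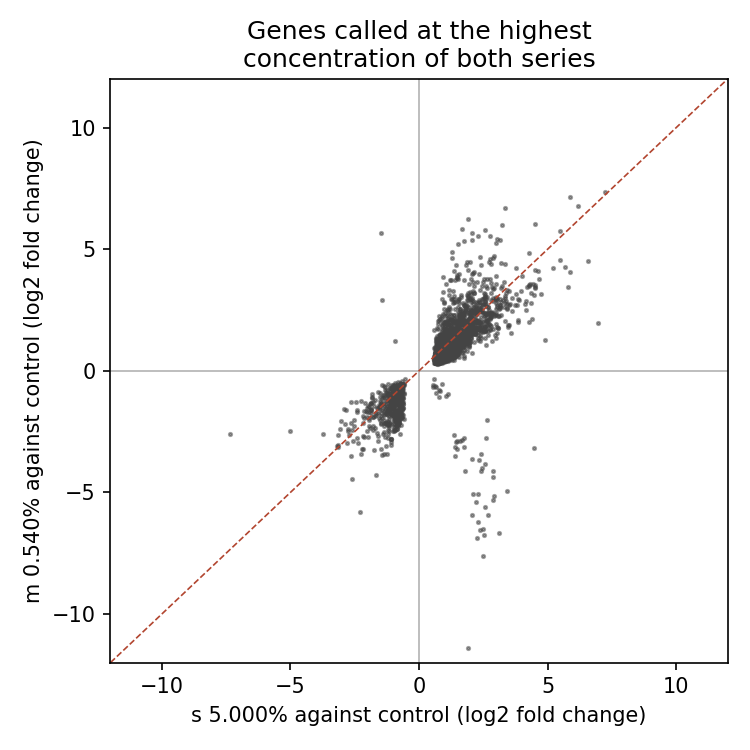
Log2 fold change at 5.000% against the s controls (x axis) and at 0.540% against the m controls (y axis) for the 2505 assembled genes that passed in both (points), with the line of equal change dashed. The 2451 genes that moved the same way lie at the lower left and upper right, and the 54 genes that moved opposite ways lie at the upper left and lower right.

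The difference between the effects at the 2 highest concentrations was tested directly as an interaction, coded as the m effect minus the s effect. It passed for 8918 of 171091 genes, 941 above and 7977 below 0, but the count and the size of the excess below 0 depended on how the libraries were scaled. Over all genes tested the median difference was -0.53 on the log2 scale, so 0 was not the middle of the genes. Relative to that median 1180 of the 8918 lay above and 7738 below, but they were called by a test against 0. With the genes centred below 0 such calls fall mostly below in any case, so this recount does not remove the shift. With scaling factors set within each series, an alternative chosen after that shift was seen, 1354 genes passed, 579 above and 775 below 0, with a median of -0.22. With relative-log-expression factors 6101 passed, 1496 above and 4605 below. Of the 180 genes higher at all 6 concentrations 55 passed. The median difference of the 180 was -0.48, against -0.32 for the 112614 genes tested in both series, from which they come. With each series fitted on its own, the median difference of these 112614 genes was -0.10. In those fits the 180 rose by medians of 2.16 at 5.000% and 1.96 at 0.540%. The size of the difference for the 180 thus also depended on the scaling. The count was 1150 without replicate 3 at 0.540% and 1824 without replicate 1 of the m controls. It was also more than 1.5 times lower without replicates 1 and 2 at 0.540% (4352 and 4900), without m control replicate 3 (5411) and without s control replicates 1, 2 and 3 (3666, 3737 and 4473).

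Without oil, the controls of the 2 series already differed. In the m controls 33664 genes were higher and 20243 lower than in the s controls, 53907 in all of 171091 tested. This split turned without a filter on low counts, 20524 higher and 26101 lower. Of the 53907, 49279 were kept in the same direction with relative-log-expression factors. Factors set within each series, chosen after the data were seen, kept 27111. Such factors do not scale the s libraries against the m libraries beyond their totals, so this setting cannot decide how well these calls hold. It shows that which genes passed depended on scaling the series against each other. The count was 29929 and 33354 without m control replicates 2 and 3, and 35144 and 34725 without s control replicates 1 and 2. A batch, spawn or day of the exposure cannot be told apart from the series.

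Libraries of the same group also differed along one main axis. The first principal component held 37.8% of the variance in the s series and 43.1% in the m series. In the s series its scores reached 241 in replicate 3 at 5.000% and 140 in replicate 1 at 2.500%, against -105 and -130 in the other libraries at 5.000%. In the m series they reached 216 in replicate 1 of the controls and 163 in replicate 3 at 0.135%. The mean gene length weighted by counts was 2728 bp in replicate 3 at 5.000% against 2946 and 2963 bp in the others, and 2845 bp in replicate 1 of the m controls against 3068 and 3059 bp. Over the 11 s libraries, the component and this length correlated with r = -0.93 (permutation p = 1.3e-04, adjusted p = 7.8e-04 over 6 relations) and rho = -0.92 (permutation p = 2.6e-04), and with r = -0.80 without the 2 libraries farthest from the median length. Over the 11 m libraries r was -0.76 (permutation p = 5.6e-03, adjusted p = 1.7e-02) and rho -0.60 (permutation p = 5.7e-02), and r was -0.26 without 2 libraries, so that relation rested on those. The permutation tests were two-sided. In the m series the component also followed the concentration, with r = -0.74 (permutation p = 1.0e-02, adjusted p = 2.0e-02) and rho = -0.84 (permutation p = 1.7e-03). The 3 libraries at 0.540% are tied as the farthest from the median concentration, and r was between -0.78 and -0.66 over the 3 choices of 2 of them to leave out. In the s series r with concentration was 0.19 (permutation p = 5.9e-01, adjusted p = 6.2e-01) and rho 0.04 (permutation p = 9.0e-01). There r ran from -0.05 to 0.90 over the 3 choices of 2 libraries at 5.000% to leave out, so it rested on which of them were kept. With total counts r was -0.30 in the s series (permutation p = 3.8e-01, adjusted p = 5.7e-01; rho -0.31, permutation p = 3.6e-01) and -0.17 in the m series (permutation p = 6.2e-01, adjusted p = 6.2e-01; rho -0.27, permutation p = 4.2e-01).

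**Figure D4:**
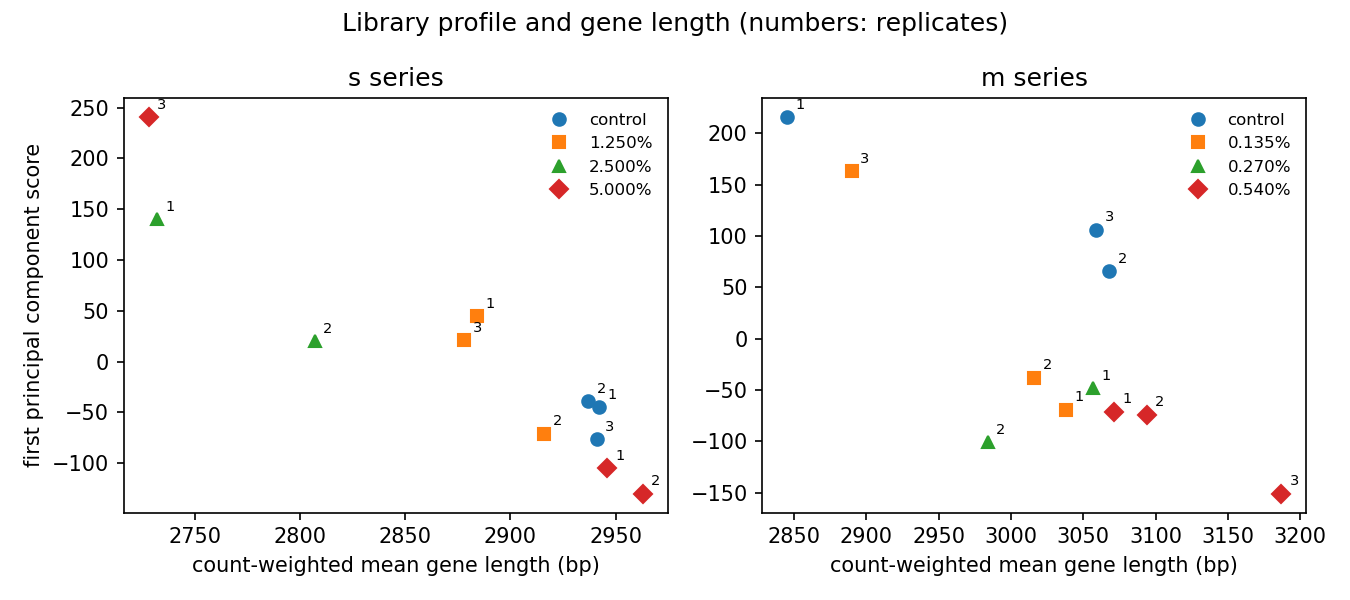
First principal component score of each library (y axis) against its mean gene length weighted by counts (bp, x axis), for the s series (left) and the m series (right), with symbols for the concentrations and numbers for the replicates. Replicate 3 at 5.000% has the lowest length of the s series, 2728 bp, and the highest score, 241.

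The authors' deposited tables of the same 6 comparisons list transcripts in place of genes. By their adjusted p under 0.05 they hold 2728 transcripts at 1.250%, 23667 at 2.500% and 13481 at 5.000%, and in the m series 610 at 0.135%, 11544 at 0.270% and 16117 at 0.540%. In the authors' deposited tables the share of these that was higher in exposed larvae was 51.8%, 42.7% and 64.7% in the s series and 63.9%, 46.6% and 49.4% in the m series. The means in these tables were weighted sums of the deposited counts, and relative to replicate 1 the weight of replicate 2, corrected for library size, was 1.99 in the authors' deposited table of 2.500% and 1.86 in that of 0.270%. In the other arms of the authors' deposited tables the weights lay between 0.891 and 1.01.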

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

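The comparison of the effects of the 2 series was planned, while the tests of mean gene length and of factors set within each series were chosen after the result was seen, and the test of total counts before.

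The effects at the highest concentrations differed between the series for 8918 genes by the interaction test, with the m effect above the s effect for 941 and below it for 7977. Of 31 ways to split the same libraries, 2 gave as many genes, the real one included. The highest other split, with 14107 genes, kept the 4 real groups together and exchanged control and exposed in the m series, so that it measured the sum of the effects and was no chance regrouping. No split drawn that mixed libraries of different groups gave as many genes as the real one. The number was raised from 21 to 31 after 2 as large were seen, and the nature of the other split was noticed only from its value, so whether chance is excluded is left open. With factors set within each series 1354 genes passed, 579 above and 775 below 0. The size of the excess of lower m effects may thus be in large part a matter of scaling. The majority stayed below 0 in each scaling run. The test was against 0, though, and with joint factors the median over all genes was itself -0.53, so this majority does not separate gene effects from the shift. No biological explanation was tested, and the 2 oils were given at different concentrations.

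Libraries of the same group were spread along the first principal component. Leaving out libraries far out on the component moved the counts both ways: up at 5.000% from 4069 to 20338 without replicate 3, down at 2.500% from 3956 to 917 without replicate 1, and down at 0.540% from 13421 to 7658 without m control replicate 1. The length covariate also moved them both ways, at 5.000% to 28434 and for the m slope from 16053 to 8196. None of these separates the spread from other traits of those libraries. Total counts correlated with the component at -0.17 in the m series and -0.30 in the s series. The m value lay under the limit set beforehand as speaking against sequencing depth. With 11 libraries per series a moderate relation stays possible, so depth is not excluded. Within groups the component followed the mean gene length, with r = -0.82 in the weaker series (m) and -0.99 in the other, which is what recovery of transcripts by length, as through RNA quality, could give. Without the 2 libraries farthest from the median length the within-group values were -0.64 and -0.96, and the pooled m value fell to -0.26. Mean length was computed from the same counts, so a change in which genes were expressed, as from a difference in developmental pace between pools, would move it too and stays open, untested.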

How the results depend on the processing

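The alternatives with mean gene length as a covariate, replicate 2 entered as a pair and factors set within each series, and all those of the shared sets of genes, were chosen after the data were seen; the others were planned, and where a value moved the cause was not tested. Of the 180 genes higher at all 6 concentrations DESeq2 kept 169, relative-log-expression factors 173 and the length covariate 180, but the replicate block kept 152, the comparison of only the 2 groups 96, and the fit without m control replicate 2 kept 124.

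DESeq2 gave 725 genes at 0.135%, 7734 at 0.270%, 13950 for the interaction and 34 genes lower at all 6 concentrations. Relative-log-expression factors gave 3920 at 0.270%. A minimum fold change of 2 gave 2368 at 2.500%, 2371 at 5.000%, 172 at 0.135%, 1158 at 0.270% and 6863 at 0.540%. Without a filter there were 1746 at 0.135%, 8478 at 0.270%, 4377 for the interaction and 275 higher at all 6. With only the 2 groups compared there were 2803 at 1.250%, 23826 at 2.500%, 120 at 0.135%, 6958 at 0.270%, 25949 at 0.540% (11661 higher), and 103 higher and 13 lower at all 6. Transcripts in place of genes gave 196 at 1.250%, 1015 at 2.500% (680 higher), 2310 at 5.000%, 174 at 0.135%, 8159 at 0.540% and 1303 moving the same way at both highest concentrations. The length covariate gave 4542 at 1.250%, 37778 at 2.500% (22027 higher), 28434 at 5.000%, 14472 for the s slope, 759 at 0.135%, 11378 at 0.270% (5271 higher), 8196 for the m slope, 5764 for the interaction, 6496 moving the same way at both highest concentrations, and 472 higher and 54 lower at all 6. In the m series that covariate is partly confounded with concentration. In the s series it is partly confounded with 1.250% and 2.500%. The mean lengths were 2884, 2916 and 2878 bp at 1.250% and 2732 and 2807 bp at 2.500%, against 2937 to 2942 bp in the controls. Replicate 2 as a pair gave 10100 at 2.500% and 18291 at 0.270%, and factors set within each series gave 1354 for the interaction. One gene at 0 counts in the exposed s libraries reversed at 2.500% with the length covariate, to 23.5 on the log2 scale, a fitted value that is no bound.

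Replicate numbers did not pair the samples: the deviations of libraries with the same number correlated between -0.35 and 0.43 in the s series and -0.46 and 0.32 in the m series. The replicate block gave 7876 at 2.500%, 1495 at 0.270%, 8924 at 0.540%, 5081 for the interaction and 25684 between the controls.

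Leaving out 1 library at a time gave 248 to 356 at 1.250%, 917 to 1833 at 2.500%, 2313 to 20338 at 5.000%, 194 to 1514 at 0.135%, 1106 to 2684 at 0.270% and 6492 to 10907 at 0.540%. It gave 2941 to 10520 for the s slope, 6696 to 13814 for the m slope, 1150 to 12910 for the interaction, 29929 to 56582 between the controls, 1662 to 5532 moving the same way at both highest concentrations, and 124 to 200 higher and 9 to 31 lower at all 6. For the slopes only control and highest libraries were left out. Where an exposed library was left out, only the comparison at its own concentration was refitted, and the shared sets took the other comparisons from the full fit. Where 1 library was left at a middle concentration it was assumed to vary like the other groups. In simulations with 200 genes changed, 1.49% and 7.46% of 1.5-fold changes were recovered at 5.000% and 0.540%. More genes passed in the real comparisons, which loosens the cut on p, so these rates do not carry over to them. The alternatives of the gene lists were not run.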

Other observations

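The tests of the genes found in the m controls were chosen after the result was seen, and the test of the repeated library after the data were seen, though what it should give was written before it was run. The splits were set before, except that the numbers drawn for the slopes and for the interaction were raised afterwards.

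A set of 102 genes was chosen by a level of at least 2 CPM in m control replicate 1. At most 2 other libraries could lie above 1/50 of that level. Their summed CPM was 12500, 720 and 107 in m control replicates 1, 2 and 3, and they were nearly absent elsewhere. Of the 102 genes, 37 had at least 100 counts in replicate 2 and 16 had as many in replicate 3. The 118-fold range among the 3 m controls, which had no oil, was favoured by choosing the set on replicate 1. That range therefore does not decide whether larvae expressed these genes and lost them with oil. The ratio of replicate 2 to replicate 1 had an SD of 0.11 on the log2 scale over 37 genes, against 0.25 over 7008 other genes, while the ratio of replicate 3 to replicate 1 had an SD of 0.38 over 16 genes. The close ratio in replicates 1 and 2 may come from 1 outside source present in different amounts, and replicate 3 does not show it as closely. The source was not identified, and 1 unusual larva in a pool or another organism stays open.

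In the authors' deposited tables more transcripts had an adjusted p under 0.05 at 2.500% (23667) than at 5.000% (13481). Entering replicate 2 as a pair, as the weight of 1.99 in that deposited table has it, raised the count of genes at 2.500% from 3956 to 10100, above the 4069 at 5.000%. The same step in the m series gave 18291 at 0.270%, above the 13421 at 0.540%, but the deposited m tables, with a weight of 1.86 at 0.270%, hold 11544 and 16117. The step thus gives an order in the m series that the deposited m tables do not have. The authors' test was not rerun, and the cause of the order in the s tables stays open, the spread of the libraries at 5.000% included.

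For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. At 1.250% the real split gave 462 genes and the highest other 43, with 1 of the 10 as large, the real one included. At 5.000% the values were 4069 and 114, again 1 of 10. At 0.540% they were 13421 and 0, also 1 of 10, and between the controls 53907 and 0, with 1 of 10. At 0.135% 2 of the 10 splits gave as many genes: the real one gave 322 and another 11178, which set m control replicates 1 and 3 and replicate 3 at 0.135% against the rest and points to a structure of the samples other than oil.

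For the m slope, 1 of 51 assignments of the concentrations gave as many genes, the real one with 16053 against 13443 for the highest other. That other assignment gave 0.540% to all 3 controls and 0 or 0.135% to the libraries at 0.540%, nearly the real order reversed. The number drawn was raised from 21 after the first shares were seen, so chance is not taken here as excluded for the m slope. For the s slope 2 of 51 assignments gave as many genes, with 4793 for the real one and 14425 for the highest other. In the first 21 assignments drawn for the s slope there were also 2, a share above 0.05, and the number was raised as far as the time limit allowed after that was seen, so the s slope is not taken here as having excluded chance. The assignment with 14425 genes gave the highest concentration to 2.500% replicate 1, 5.000% replicate 3 and 1.250% replicate 3, the first 2 being the s libraries of lowest mean gene length, and points to a structure of the samples.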
